A study of Homo sapiens with 4 samples.

How the data were processed

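Total RNA of KYSE 170 cells was measured on 4 arrays, 2 from cells transfected with STMN1 in pCMV6 and 2 from cells with the vector alone. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with a mirVana kit and labelled with Cy3 in a 1-colour Agilent procedure, and the submitters' processing notes name Agilent Feature Extraction 10.7.1.1. The identifiers of the value table are transcript clusters, a form used for another manufacturer's arrays. The labels and the identifiers therefore disagree about the platform, and which of them is right is left open.

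The authors deposited 1 value per transcript cluster and array, on a log2 scale, as judged from the values themselves, which run from 1.64 to 19.93 with array medians from 3.60 to 3.72. The background correction, summarisation, normalization and filters behind these deposited log2 values are not given in the sources used here. There were 0 missing values and no detection flags, so which clusters lay above background is unknown, and low values hold an unknown share of background that shrinks differences between groups. Differences are on the deposited log2 scale and folds assume that scale. The 75th percentiles of the arrays ranged over 0.083 (log2), below the tolerance of 0.1 fixed before the data were examined, so values were used as deposited.

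Of 60789 clusters, the platform annotation lists 1 gene symbol for 21225, several for 1288 and none for 38276. Symbols were updated through gene identifiers. Clusters listed for several genes, or for none, were tested under their identifier and not given a gene name. The only cluster listing STMN1 also lists MIR3917, and it is given by its identifier. Clusters whose mean over the 4 arrays lay in the lowest 30% (below 3.29) were left out. Each gene was represented by its cluster with the highest mean. This left 42350 features, of which 16819 were named genes and 25531 were not. H2BC11 was the only gene named here with more than 1 cluster; its dimmer cluster differed by 0.65 and the brighter, used here, by 1.07.

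The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 group coefficient, two-sided, prior degrees of freedom 3.13), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Gene lists were compared with limma's camera with a preset correlation of 0.01, adjusted over the 32 lists, of whose 1015 symbols 781 were in the tested features. The result of 1 of these lists, which did not pass, is not reported here. The estimated-correlation version of camera and limma's fry were run on the same values. Named genes were chosen by a rule fixed before the data were examined. STMN1 came first, then the 10 largest rises and falls that passed with non-overlapping groups. Where fewer passed, as here in both directions, each was filled by smallest unadjusted p among named genes with a fold of at least 2. For each called list up to 4 members with the smallest p that went the list's way followed. Other members named in the text, such as those passing adjusted over a list alone, were chosen after their values were seen.

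The alternatives were quantile normalization, subtraction of each array's median, no filter or a filter at 50%, the mean of a gene's clusters, an intensity trend, a robust prior, no variance moderation, array weights, an offset of 16 on the linear scale, the replicate number as a block, a test against a fold of 1.5, and each array left out in turn. Before use, the gene test and the list test were tested on simulated data for the comparison of STMN1 overexpression with empty vector, on 42350 features. Of 50 genes changed by each fold, 0% were recovered at 2-fold, 62% at 4-fold, 96% at 16-fold and 100% at 256-fold, with 6 unchanged features called. All were planted in the same simulated data, where larger changes ease the adjusted cutoff for smaller ones. Lists shifted by 0.3 on the log2 scale were all called (100%), as were 0.345% of the others. The simulated genes were drawn independently, so the list result holds for uncorrelated genes.

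Chromosomes and gene order came from a RefSeq gene table of GRCh38.p14. No build is named for the arrays, so no coordinates are given. Windows of 20 neighbouring genes were fixed before their result was seen; windows of 50 and 100 genes were added afterwards. Each window spread was set against 1000 shuffles of gene order. Chromosomes 20, 21 and 22 were not analysed here, apart from 2 genes placed there, so the gene lists are tested without the 69 list symbols located on these chromosomes, and "all placed genes" leaves these chromosomes out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. GC content and probe positions were not analysed here, because no genome sequence was used.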

Results

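Gene expression was measured on 4 arrays of KYSE 170, a human cell line from an esophageal squamous cell carcinoma. The cells had been transfected with a pCMV6 plasmid carrying the whole STMN1 coding cDNA, or with the empty plasmid, and stably transfected cells were kept under G418. STMN1 encodes stathmin, a phosphoprotein that binds tubulin and destabilises microtubules. Each group held 2 arrays, labelled as biological replicates 1 and 2. Whether the replicates were separate clones or repeat cultures of 1 line is not given in the sources used here, so p-values measure the spread between these arrays, which may be partly technical. The question the design poses is which transcripts differ between cells carrying extra STMN1 and cells carrying the vector alone. The deposited table held 60789 transcript clusters, of which 42350 features entered the test, 16819 of them named genes. Replicates correlated at Pearson r = 0.991 in the group labelled STMN1 overexpression and 0.989 in the control group, across all features, which are not independent replicates. Mean r within groups exceeded mean r between groups by 0.0007, less than the spread of 0.0013 (SD) between the 2 within-group values. The number of arrays limits the precision of every value below.

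STMN1 itself was not higher on the arrays labelled STMN1 overexpression. It was represented by 1 transcript cluster (TC01002383.hg.1), listed for both STMN1 and the microRNA gene MIR3917. The cluster read 5.86 and 5.77 on the overexpression-labelled arrays (log2, mean 5.82 ± 0.064 SD, n = 2). On the control arrays it read 6.11 and 6.13 (mean 6.12 ± 0.018 SD, n = 2). The difference was -0.30 on the log2 scale (SE 0.14), 1.23-fold lower, and it did not pass (limma adjusted p = 0.914). An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. The measured direction opposes the label, so the groups are called by their labels throughout, and every direction below reads "arrays labelled STMN1 overexpression" against "control arrays". Where the cluster's probes lie on the transcript is not known here, so the reading does not settle how much transfected STMN1 the cells carried.

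No feature passed the limma test at an adjusted p of 0.05, and the smallest adjusted p was 0.144. At an unadjusted p under 0.05 there were 2550 features, 1102 higher and 1448 lower on the arrays labelled STMN1 overexpression, where chance alone gives about 2118. A fold of at least 2 was met as well by 295 of them, 111 higher and 184 lower. Among named genes the same 2 criteria were met by 113, of which 33 were higher and 80 lower. The arrays of the 2 groups did not overlap for 13103 features (30.9%), against 33.3% expected by chance. In simulated data of this size the test recovered 0% of genes changed 2-fold, 62% of those changed 4-fold and 96% of those changed 16-fold. It called 0 features when nothing was changed. The fold sizes, up to 256-fold, were planted together, and larger changes ease the adjusted cutoff for smaller ones. The arrays differ from that setting, since the unnamed cluster TC03003290.hg.1 did not pass at 377-fold lower (limma adjusted p = 0.144). The recovered shares therefore do not show that 4-fold to 16-fold changes are absent here.

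Among named genes with a fold of at least 2, the 10 with the smallest p-values on the higher side are given here, and none of them passed the adjusted threshold. INHBE, which encodes an inhibin beta chain, measured 6.36 ± 0.046 on the arrays labelled STMN1 overexpression against 4.80 ± 0.12 on the control arrays (log2 mean ± SD, n = 2 each). Its log2 difference was 1.56 (SE 0.15, limma adjusted p = 0.545). NUPR1, a stress-induced chromatin protein, differed by 1.68 (SE 0.20), and ATF3, a stress-induced transcription factor, by 1.03 (SE 0.14). GDF15, a secreted stress cytokine, differed by 1.23 (SE 0.16), and SLC1A4, a neutral amino acid transporter, by 1.21 (SE 0.15). The widest gap was at ANGPTL5, an angiopoietin-like secreted protein, at 6.90 ± 0.64 against 3.82 ± 0.16 (log2 mean ± SD, n = 2 each), or 8.49-fold. Its control level was dim, and the log2 difference was 2.18 with an offset of 16 added on the linear scale, against 3.09 without, so the fold depends on how background is treated. CLIC4, an intracellular chloride channel protein, differed by 2.01 (SE 0.21). CSTA, which encodes the keratinocyte protease inhibitor cystatin A, differed by 1.44 (SE 0.17). The noncoding RNA HEIH and the Wnt pathway regulator TCIM differed by 1.06 (SE 0.14) and 1.33 (SE 0.19), the latter by 0.82 with the offset of 16.

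On the lower side, the 10 genes chosen the same way, again without passing, held 3 guanylate-binding proteins, which are interferon-induced GTPases of cell-autonomous immunity. GBP2 measured 6.40 ± 0.14 on the arrays labelled STMN1 overexpression against 8.75 ± 0.025 on the control arrays (log2 mean ± SD, n = 2 each). That is a log2 difference of -2.35 (SE 0.15), 5.11-fold lower (limma adjusted p = 0.249). GBP3 differed by -1.92 (SE 0.19) and GBP6 by -1.31 (SE 0.15). RTP4, another interferon-induced gene, differed by -1.33 (SE 0.14), or -0.80 with the offset of 16. CFI, a complement regulator, differed by -1.60 (SE 0.16). SLC27A2 and ACSL5, which activate long-chain fatty acids as acyl-CoA esters, differed by -2.19 (SE 0.17) and -1.66 (SE 0.19). The adhesion receptor gene ADGRF1 differed by -1.56 (SE 0.14), the endosomal recycling subunit VPS35L by -1.49 (SE 0.15) and the kinase TNIK by -1.45 (SE 0.17). All 20 of these genes kept their direction under the alternatives tried, and none was called under any of them.

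**Figure D1:**
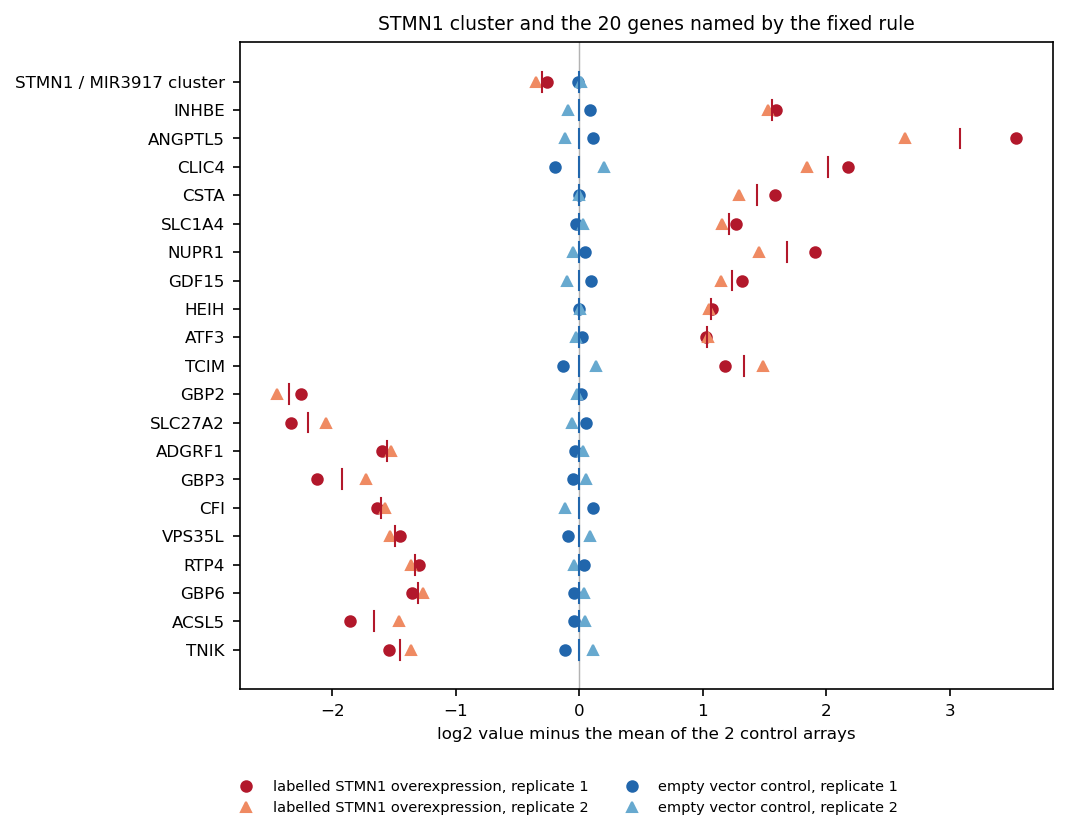
Log2 values of the STMN1 cluster and of 20 named genes on each of the 4 arrays, minus the mean of the 2 control arrays; circles are replicate 1, triangles replicate 2, red and orange the arrays labelled STMN1 overexpression, blue the control arrays, and vertical ticks the group means. The STMN1 cluster sits at -0.30, while ANGPTL5 sits at 3.09 and GBP2 at -2.35; none of the 21 rows passes the adjusted threshold.

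Of 32 gene lists fixed before the data were examined, 9 passed limma's camera test with its preset inter-gene correlation, 4 higher and 5 lower on the arrays labelled STMN1 overexpression. None of the 9 passed with an estimated correlation (adjusted p from 0.525 to 0.836) or by fry, which tests whether a list's genes move on balance 1 way (smallest adjusted p = 0.149). For the epithelial and squamous lists the estimated correlation was -0.012 and 0.016, near the preset 0.01. Their unadjusted camera p still rose from 1.5e-07 to 0.0276 and 0.0392, so correlation between genes does not account for those losses. With an estimated correlation camera uses only the residual degrees of freedom of 4 arrays, which leaves little power over 32 lists. The estimate was larger for other called lists, at 0.314 for interferon, 0.374 for cholesterol and 0.783 for G1/S, where correlation may have made the preset p-values too small. The preset test also called 10 of the 32 lists for replicate 1 against replicate 2, and 4 for the split with numbers crossed. Its p-values below are therefore not by themselves a sign of a group difference. No member of any list passed when adjusted over all genes, so the counts of members below are at unadjusted p under 0.05 or adjusted over the list alone. The STMN1 cluster did not show the labelled overexpression, and the directions below follow the labels only.

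The unfolded protein and integrated stress response list passed camera as higher on the arrays labelled STMN1 overexpression. Of 28 members measured, 23 lay above 0, with a median log2 difference of 0.62 or 1.54-fold (camera adjusted p = 2.97e-12; adjusted p = 0.525 with an estimated correlation). At an unadjusted p under 0.05, 15 members were higher and 1 was lower, and adjusted over the list alone 8 passed as higher and 1 as lower. PPP1R15A, which recruits a phosphatase to eIF2alpha, measured 8.09 ± 0.028 against 6.70 ± 0.33 (log2 mean ± SD, n = 2 each). Enzymes of serine and cysteine synthesis were among the members, with PSAT1 at a difference of 1.13 (SE 0.21) and CTH at 0.86 (SE 0.14). SLC7A11, the cystine transporter subunit, measured 2.15-fold higher, while SLC7A5 differed by 0.69 (SE 0.16) and HERPUD1 by 0.68 (SE 0.16). ATF6, a stress sensor of the endoplasmic reticulum membrane, was the member that passed as lower, at -0.75 (SE 0.17). DDIT3, the transcription factor CHOP, measured 7.58 against 6.46 and the chaperone HSPA5 14.85 against 14.23, and neither passed.

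The interferon-stimulated list passed camera as lower on the arrays labelled STMN1 overexpression. Of 37 members, 33 lay below 0, with a median log2 difference of -0.54 or 1.45-fold lower (camera adjusted p = 1.12e-12; adjusted p = 0.694 with an estimated correlation). Without replicate 1 of the overexpression-labelled group the median was -0.31, and over the 4 fits with 1 array left out it ran from -0.66 to -0.31. At an unadjusted p under 0.05, 14 members were lower and 1, BST2, was higher, and none passed adjusted over the list alone. IFI6 measured 7.56 ± 0.59 against 9.76 ± 0.93 (log2 mean ± SD, n = 2 each), a wide spread within both groups. IFIT3 differed by -0.84 (SE 0.15), IFI44 by -1.14 (SE 0.25) and the RNA-sensing synthetase OAS1 by -0.96 (SE 0.21). The list's mean differed by -0.52 between groups and by 0.37 between the 2 overexpression-labelled arrays. Antigen presentation genes, many of them also interferon-induced, had a median of -0.07 over 20 members and did not pass (camera adjusted p = 0.161).

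The squamous keratinocyte and epithelial junction lists passed camera as lower on the arrays labelled STMN1 overexpression. Among 34 squamous keratinocyte genes the median log2 difference was -0.24 and 25 lay below 0 (camera adjusted p = 1.18e-06; adjusted p = 0.525 with an estimated correlation). Without control replicate 1 the squamous median was -0.14, with the call kept. Adjusted over the list alone, 8 members passed as lower and 1, CSTA, as higher. Keratins made up 7 of the 8, with the last being the membrane protein gene EMP1. KRT13, a keratin of the suprabasal esophageal lining, measured 11.38 ± 0.24 against 13.33 ± 0.33 (log2 mean ± SD, n = 2 each), 3.85-fold lower. The basal keratins KRT5, KRT14 and KRT15 differed by -2.04 (SE 0.36), -0.91 (SE 0.15) and -1.01 (SE 0.15). Epithelial junction genes had a median of -0.36 over 27 members, 21 of them below 0 (camera adjusted p = 1.18e-06; adjusted p = 0.525 with an estimated correlation). Their lowest p-values were at GRHL3, an epithelial transcription factor, at -0.89 (SE 0.18), and at the tight junction genes CLDN4 at -0.51 (SE 0.14) and OCLN at -0.54 (SE 0.16). No junction gene passed adjusted over the list alone. Mesenchymal markers did not pass, with a median of -0.02 over 19 members (camera adjusted p = 0.178), but were called lower with the dimmest 50% of features left out (median -0.14, adjusted p = 0.018). FN1, fibronectin, passed as lower adjusted over that list alone at -1.02. Columnar or glandular epithelium markers did not pass either, at a median of -0.04 over 16 members, with CEACAM5 passing as lower adjusted over that list alone at -1.23.

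Proliferation genes passed as higher, but the calls rested on replicate 2 of the group labelled STMN1 overexpression. The median log2 difference was 0.24 over 32 genes of G1/S and DNA replication (camera adjusted p = 0.0132), 0.12 over 35 genes of mitosis and G2/M (0.0257) and 0.50 over 13 histone genes (0.00151). With an estimated correlation the adjusted p was 0.836 for the first and second of these lists and 0.694 for the histones. Without that array the G1/S median was -0.17 and the list was called lower (camera adjusted p = 0.00455), while the mitosis list (0.812) and the histones (0.707) lost their calls, at medians of 0.036 and 0.041. Without replicate 1 of that group the medians were 0.62 for G1/S, 0.26 for mitosis and 0.82 for the histones. Without control replicate 1 the G1/S list (0.18) and the mitosis list (0.173) lost theirs too. Over the 4 fits with 1 array left out, the adjusted p ran from 3.03e-19 to 0.18 for G1/S, from 8.72e-07 to 0.812 for mitosis and from 1.45e-11 to 0.707 for the histones. FOXM1, a transcription factor of the G2/M programme, measured 11.35 and 12.16 against 10.80 and 10.96, and ECT2, a cytokinesis factor, 10.15 and 10.92 against 9.93 and 9.59. For TK1, thymidine kinase, the values were 10.56 and 11.53 against 10.45 and 9.96. H2BC11, a histone H2B gene, measured 11.21 and 12.72 against 10.99 and 10.80. No member of these 3 lists passed adjusted over its list alone. NEK2 and NUF2 of the mitosis list went the other way, at -0.70 and -0.69. Both lie on chromosome 1, whose genes lay lower as a whole, as described below. Without the 4 mitosis members on that chromosome the median was 0.14 and the call was kept (camera adjusted p = 0.00155).

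Cholesterol biosynthesis genes and YAP/TEAD targets passed as lower. The cholesterol list had a median of -0.23 over 23 members (camera adjusted p = 0.000414; adjusted p = 0.694 with an estimated correlation). Without genes of chromosome 1 the median was -0.15 and the call was kept (0.0036). It lost its call without replicate 1 of the overexpression-labelled group (median -0.083, adjusted p = 0.427) and without control replicate 2 (median -0.21, adjusted p = 0.0595). ELOVL6, a fatty acid elongase controlled by the same regulators, differed by -0.88 (SE 0.15) and was the member that passed adjusted over the list alone. MSMO1 differed by -0.71 (SE 0.16) and INSIG1 by -0.61 (SE 0.20). YAP/TEAD targets had a median of -0.12 over 28 members, 21 of them below 0 (camera adjusted p = 0.00297; adjusted p = 0.694 with an estimated correlation). That call was lost without control replicate 2 (median -0.061, adjusted p = 0.354) and when genes of chromosome 1 were left out (median -0.056, adjusted p = 0.141). The median was -0.33 without control replicate 1 and -0.23 without replicate 1 of the overexpression-labelled group. NT5E, an ectonucleotidase, differed by -1.01 (SE 0.18), AMOTL1 by -0.74 (SE 0.17) and the growth factor TGFB2 by -0.71 (SE 0.16).

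**Figure D2:**
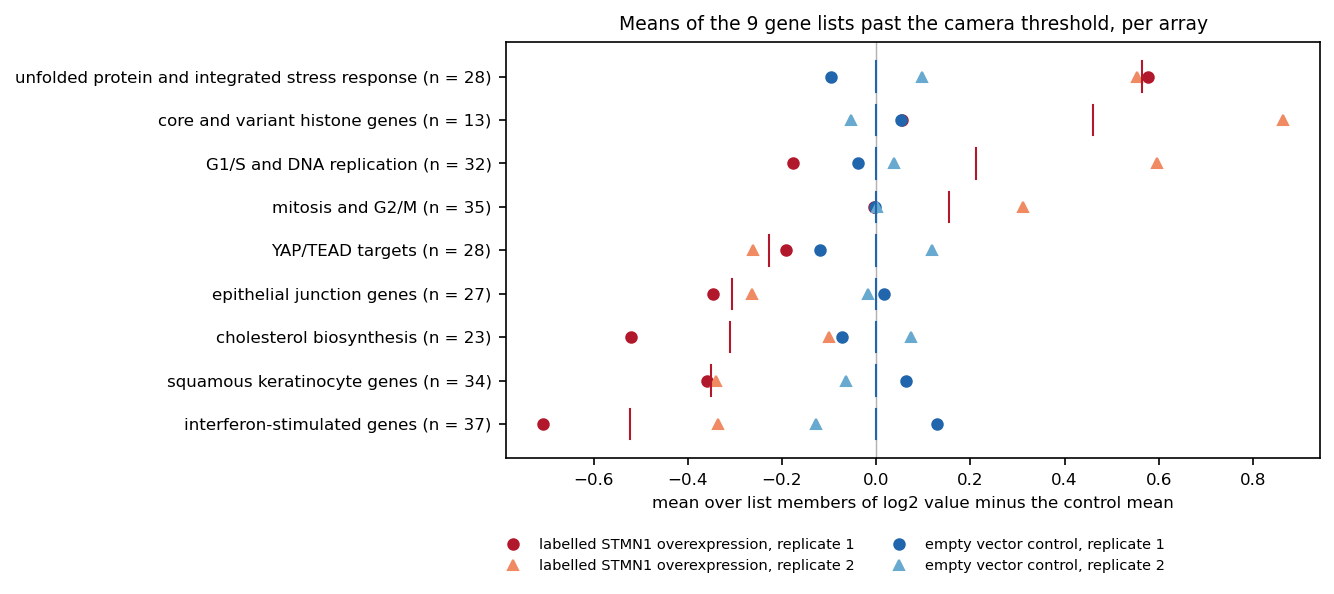
Mean over the members of each of the 9 lists past the camera threshold, per array, of the log2 value minus the control mean; symbols and colours mark the array as in the legend, and vertical ticks are group means. The stress response list sits at 0.58 and 0.55 on the arrays labelled STMN1 overexpression, whereas the G1/S list sits at -0.18 on 1 of them and 0.60 on the other.

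Microtubule and tubulin genes, the class closest to stathmin's function, did not pass. Their median log2 difference was 0.04 over 35 members (camera adjusted p = 0.632), with 23 above 0. The value rested on single arrays, since without replicate 1 of the overexpression-labelled group the median was 0.13 and the list was called higher (0.0319), while without replicate 2 it was -0.074 and uncalled (0.307). KIF5B, a kinesin heavy chain, differed by 0.71 (SE 0.25), and the microtubule-binding genes MAP7 and MAPRE2 differed by -0.46 (SE 0.15) and -0.52 (SE 0.19). The other lists past no threshold had camera adjusted p-values from 0.0987 to 0.947. Some gained a call when a setting or 1 array was changed. Ribosomal proteins were called higher with quantile normalization (0.00704), with the offset of 16 (0.0278), without replicate 1 of the overexpression-labelled group (0.0158) and without control replicate 2 (0.0329). Oxidative phosphorylation was called higher without that same overexpression-labelled array (0.0158) and the NF-kappaB list without control replicate 2 (0.0489). TGF-beta and SMAD targets were called lower without replicate 2 of the overexpression-labelled group (0.0179). Among signalling lists, the medians were 0.15 for NF-kappaB and inflammatory cytokine genes, -0.125 for TGF-beta and SMAD targets, 0.014 for immediate early genes, -0.013 for the PI3K and AKT pathway and -0.016 for Wnt and Notch. In the adhesion and matrix lists they were -0.059 for integrins and focal adhesion and -0.11 for extracellular proteases and inhibitors. Against that last median, TIMP4, MMP10 and MMP1 passed as higher adjusted over the list alone, at 1.06, 0.78 and 0.74, and CTSL as lower at -0.85. By the same adjustment CCL20 of the NF-kappaB list passed at 1.08, ATF3 passed in both the immediate early and the p53 list, and in the NRF2 list SLC7A11 passed as higher while GCLM and ALDH3A1 passed as lower at -0.93 and -1.43. For metabolism and biosynthesis they were -0.0018 for NRF2 targets, 0.079 for ribosomal proteins, 0.046 for oxidative phosphorylation and 0.0018 for hypoxia and glycolysis, where camera's direction was lower. The p53 targets had a median of -0.030 with camera's direction higher, apoptosis regulators -0.058 and cancer-testis genes 0.016. Markers of other cell types did not pass, with medians of 0.077 for fibroblast, -0.012 for endothelial and 0.083 for neural genes. Haematopoietic markers had a median of 0.0093 with camera's direction lower, and CD68 passed as lower adjusted over that list alone at -0.71.

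Genes of chromosome 1 lay lower as a whole on the arrays labelled STMN1 overexpression, a comparison made after the data were examined. Of 1683 named genes on that chromosome 64.8% lay below 0, against 46.8% of all placed genes, and the median was -0.086 against 0.020 for genes of other chromosomes. The replicate 1 pair gave -0.084 and the replicate 2 pair -0.092, while the medians between replicates were 0.0040 in the overexpression-labelled group and -0.027 in the control group. Cut into windows of 50 genes in gene order, which leaves the last 33 genes in no window, 27 of the 33 windows of chromosome 1 had medians below 0, and the 6 others were all among the first 7. The lowest window, from VASH2 to ACBD3, had a median of -0.30 with 41 of 50 genes below 0. STMN1 lies in 1 of those first windows, from HTR1D to LIN28A, and its 20 nearest measured neighbours had a median of 0.056. The guanylate-binding protein genes lie in the window from DNAJB4 to ZNF644, whose median was -0.19.

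**Figure D3:**
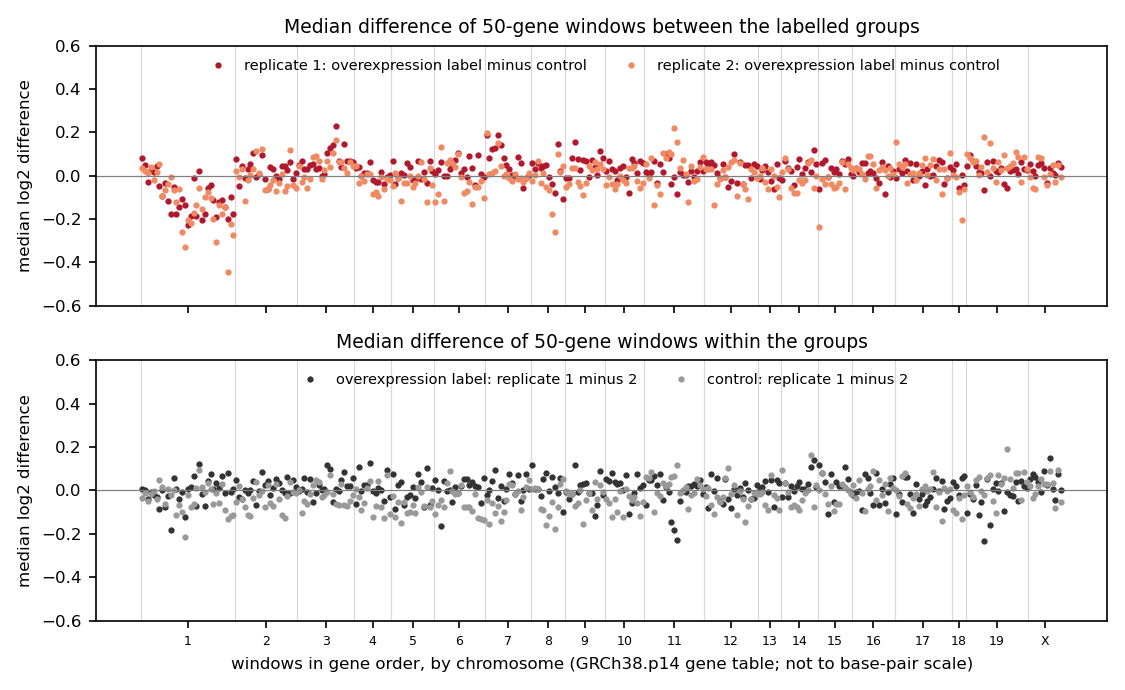
Median log2 difference of windows of 50 neighbouring genes in gene order, for the 2 pairs of arrays between the labelled groups (upper panel) and for the 2 pairs within groups (lower panel); grey lines separate chromosomes. Of the 33 windows on chromosome 1, 27 sit below 0 in each pair between groups, with -0.20 and -0.44 in the lowest window; 16 do so between the overexpression-labelled replicates and 23 between the control replicates, whose difference is below 0 in 209 of all 324 windows.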

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

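Alternatives were fixed before the data were examined, except that the restriction to named genes, and for the list test also the intensity trend, the mean of a gene's clusters and the offset of 16, were chosen after seeing the data. At an adjusted p of 0.05 the count of higher features was 0 under every alternative, and the count of lower features was 0 except with a control array left out, where leaving out each array in turn gave 0 to 2. The features were TC03003290.hg.1 and TC03003289.hg.1 without control replicate 1, and the former without control replicate 2; both are unnamed, and the lone array left in the control group is assumed to vary like the other group. The 2550 features at an unadjusted p under 0.05 became 226 when tested against a fold of 1.5 and 1524 among named genes alone. The 295 with a fold of at least 2 became 129 without variance moderation, 151 with the offset of 16, 115 among named genes alone, and 415 to 810 with 1 array left out. The difference at the STMN1 cluster kept its sign and stayed uncalled under all 16 alternatives, as did every named gene in 935 recomputed values. Lists called higher fell from 4 to 0 and lists called lower from 5 to 0 both with an estimated correlation and by fry. Both tests have little power with 4 arrays, so these losses do not by themselves show that correlation between genes made the calls. Nor do they exclude it, since the estimated correlation was far above the preset 0.01 for several lists. It was 0.314 for interferon, 0.373 for mitosis, 0.374 for cholesterol, 0.654 for the histones and 0.783 for G1/S. With arrays left out in turn, the lists called higher ranged from 1 to 7 and those called lower from 3 to 8. Without replicate 2 of the group labelled STMN1 overexpression the G1/S list turned to -0.17 and camera's direction for mitosis turned to lower at a median of 0.036. Over the 4 arrays left out in turn the medians ran from -0.17 to 0.62 for G1/S and from 0.036 to 0.26 for mitosis. The 2 arrays of that group disagreed, with G1/S list means of -0.18 on replicate 1 and 0.60 on replicate 2. Which of them departs from the group's usual level cannot be told from these arrays. The mitosis list was also lost with the intensity trend. The stress response, interferon, squamous and epithelial lists kept call and direction in all 4 leave-one-out fits and under every other camera setting with the preset correlation, although the interferon and squamous medians moved by over 1.5 times, ranging from -0.66 to -0.31 and from -0.32 to -0.14 with 1 array left out. Replicate numbers were shared across groups but no label ties them to a batch, and with only 2 pairs the correlation of same-numbered deviations was 0.138. With the replicate number as a block there were 0 features at an adjusted p of 0.05, 288 at an unadjusted p under 0.05 with a fold of at least 2, and 4 higher and 5 lower lists, and all 9 calls were kept. No background signal or detection flag was used here, so what the signal over background limits is unknown for dim features.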

Other observations

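The tests on families, unnamed features, splits of the arrays, replicate spread, the STMN1 cluster and chromosome 1 were chosen after the results were seen; the test of quantile normalization and that of 20-gene windows were planned before their results, and those of array pairs and of lists without chromosome 1 after the chromosome 1 pattern had been noticed but before their own results.

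Beyond the fixed lists, all 7 guanylate-binding protein genes measured lay below 0 on the arrays labelled STMN1 overexpression, with a median log2 difference of -1.31 and 5 at an unadjusted p under 0.05. GBP1 measured 6.94 ± 0.35 against 8.52 ± 0.11 and GBP4 4.19 ± 0.078 against 5.43 ± 0.23 (log2 mean ± SD, n = 2 each). Metallothioneins, small metal-binding proteins, lay below 0 in 13 of 14 cases, with a median of -0.43 and 1 at an unadjusted p under 0.05. The median was -0.73 on replicate 1 and -0.16 on replicate 2 of the overexpression-labelled group, against 0.20 and -0.20 on the control arrays. By these medians only the replicate 1 pair showed a fall. Small nucleolar RNAs, many of them guides of ribosomal RNA modification, lay below 0 in 157 of 204 cases with a median of -0.20. The median was -0.17 and -0.20 on the overexpression-labelled arrays and 0.058 and -0.058 on the control arrays. The cases include numbered copies such as SNORD116-15 and SNORD116-23, so they are not all independent. The chromosome 15 window of 50 genes from CHEK2P2 to SNORD115-16 had a median of -0.18, at -0.060 in the replicate 1 pair and -0.23 in the replicate 2 pair. MicroRNA features had a median of 0.031. The directions of these 4 families held with quantile normalization and with each array's median subtracted.

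Wide differences lay at unnamed clusters. TC03003290.hg.1 measured 6.05 and 5.91 on the arrays labelled STMN1 overexpression against 13.85 and 15.22 on the control arrays, a log2 difference of -8.56 (SE 0.45, limma adjusted p = 0.144). TC03003289.hg.1 measured 4.73 and 5.11 against 11.46 and 12.53, a difference of -7.07 (SE 0.38, limma adjusted p = 0.144). In the other direction TC09000447.hg.1 measured 7.17 and 6.50 against 2.57 and 3.13 (limma adjusted p = 0.353). Those control readings lie below 3.29, the mean level under which clusters were left out, so no size is given for that difference. Which transcripts these clusters detect is not known here.

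The STMN1 cluster was not higher on the arrays labelled STMN1 overexpression. If the cluster reads the transgene, an exchange of arrays would hide a 2-fold overexpression only if some split of the 4 arrays showed it. The largest difference over the 3 splits was 0.30, that of the labelled split, with 0.058 as the highest of the others. If the cluster does not read the transgene, no split could show it, and an exchange of arrays stays open. A ceiling is also argued against, since the cluster's mean lay at percentile 73.2 of the tested features. Probes outside the transfected cDNA, or shared between the 2 genes listed for the cluster, may keep it from reading the transgene, and this cannot be told apart from a lost or silent transgene without probe positions. A label wrong for a whole set of cells, or an absence of overexpression at the RNA level, stays open as well.

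The 9 list calls were weighed against technical sources. Scaling left in the deposited values is argued against, because 9 of 9 lists kept call and direction after quantile normalization. Without chromosome 1, 8 of 9 lists kept theirs. Camera sets a list against the other features, so genes that lie lower could raise a higher list only by lowering that background. The 4 higher lists kept their calls without chromosome 1 (camera adjusted p from 9.73e-12 to 0.0145). The 5 lower lists test that chromosome as a source more directly. The interferon (camera adjusted p = 9.73e-12), squamous (1.2e-05) and epithelial lists (3.45e-05) kept their calls, which argues against it for these lists. The cholesterol call was kept with its median shrunk from -0.23 to -0.15. YAP/TEAD targets lost theirs. For differences between preparations, the group difference in list means was at least 2.73 times the larger replicate difference for the stress, squamous and epithelial lists, at most 0.569 times for the cell cycle and histone lists, 0.738 for cholesterol and 0.956 for YAP/TEAD targets, where preparation is a candidate explanation, and 1.41 for interferon, which leaves that list open; 2 uncalled lists, mesenchymal at 15.8 and columnar at 3.21, also exceeded 2. An earlier criterion, whether another split of the arrays called the list, was set aside after its result was seen: no other split called the stress (smallest adjusted p = 0.128), squamous (0.353), epithelial (0.552) or YAP/TEAD lists (0.069), while another split called the G1/S (1.02e-08), mitosis (0.00256), histone (0.000258), cholesterol (0.00192) and interferon lists (0.000154), so that under it interferon too would go with preparation; the split of replicate 1 against replicate 2 called 10 of the 32 lists and the crossed split 4, against 9 for the labelled split. Any state that both arrays of a group shared, such as clone, culture density or passage, stays confounded with STMN1, and the directions rest on labels that the STMN1 cluster did not bear out.

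Neighbouring genes differed together between the labelled groups, above all on chromosome 1, where they lay lower. Some windows of other chromosomes lay higher. The highest window of 50 genes, from LOC90246 to STAG1 on chromosome 3, had medians of 0.23 in the replicate 1 pair and 0.17 in the replicate 2 pair. The next, from FAM20C to OCM on chromosome 7, had 0.19 and 0.20. The spread of 20-gene window medians was 1.814 times that of shuffled gene orders under the labelled split, against 1.376 at most under the others, with a permutation p = 0.001 in every split, the smallest that 1000 shuffles can give. A chance pattern of single arrays is argued against, since 50-gene window medians of pairs sharing no array correlated at r = 0.543 across windows between groups with matched numbers, 0.472 with crossed numbers and -0.035 within groups, a gap of 0.578 for the matched pairs, although genes and windows are not independent replicates. Over the 42350 single features, r was 0.128 matched, -0.0099 crossed and 0.138 within groups. Over named genes it was 0.20, 0.195 and 0.0062 in the same order. The gap thus held for windows and named genes, and not over all features. Without chromosome 1 the 20-gene ratio was 1.429 under the labelled split, 1.386 with numbers crossed and 1.231 for replicate 1 against replicate 2. There the 20-gene spread hardly set the labelled split apart from the crossed one. The 50-gene ratios were 1.654, 1.498 and 1.264 in the same order, and the 50-gene r was 0.287 matched and 0.201 crossed. Of the 20 lowest windows, 17 lay on chromosome 1. Regional differences such as copy number between the stable lines may account for it and would mean that the lines differ by more than the transgene, but DNA was not measured here, and shared regulation or a bias in GC content stays open.

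At an unadjusted p under 0.05 the labelled split gave 2550 features and 2 of the 3 splits, itself included, gave as many. The highest other, replicate 1 against replicate 2, gave 3239. With a fold of at least 2 as well, the labelled split gave 295 features, replicate 1 against replicate 2 gave 213 and the crossed split 130. With 3 splits no share under 0.05 can be reached.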
